A study of Homo sapiens with 6 samples.

How the data were processed

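RNA sequencing was done on 3 libraries of parental C4-2B cells and 3 of the abiraterone-selected subline, as the labels group them by cell line. Per the labels' protocols, the selected cells were passaged in 1 to 20 µM abiraterone, kept in 5 µM, and are given as passage 15 to 18. Parental cells were passaged alongside in 1% DMSO. The parental libraries are nevertheless given as passage 0, so passage number cannot be told apart from cell line. Both lines grew in medium with 10% serum. The protocol mentions 10 µM abiraterone before RNA extraction in a wording that leaves open whether both lines received it. Libraries came from 1 µg of total RNA and were read as 50 bp single ends. The protocol names 2 library kits, an mRNA kit and a stranded total RNA kit, without saying which libraries used which; this affects genes whose RNA has no poly(A) tail. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

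A single table was used, the authors' comparison of conditions C and V by DESeq2. It has no column per library, so no test across libraries could be run here and depth per sample is unknown. The mean of normalised counts over all samples is a signal value that the authors computed, per the file headers. The log2 fold change of C over V is the authors' maximum likelihood estimate, per the file headers. Its standard error and the Wald statistic are the authors' score columns, per the file headers. The p-value is from the authors' Wald test and the adjusted p-value from their Benjamini-Hochberg correction, per the file headers. Quality control with FastQC and the use of Cufflinks 2.2.1 are named in the submitters' processing notes, without their role. The aligner, the read counter and the genome build are not given in the sources used here. How many libraries stand behind C and V is not stated in the header.

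Checks on the table showed that it is a selected list. All 6018 genes have p under 0.05 and an absolute log2 fold change of at least 1.20. A gene not listed may therefore have missed either limit, and its absence says nothing about its level. The adjusted p at the largest p was 2.04 times that p, which places about 48.9% of the genes given an adjusted p at or below it. The Wald statistic equalled the fold change over its standard error, and 5767 of 5767 p-values recomputed from it lay within 1% of the listed ones. For 29 genes p is listed as 0. For 4 genes, CYP17A1 among them, the adjusted p is 0 beside a p above 0, and it was read as not given. The 638 listed genes that were not called comprise these and those with an adjusted p of 0.05 or more.

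Gene identifiers are Ensembl IDs with symbols as the table gives them; 5989 matched the gene name table. Gene types and positions came from GENCODE release 29 (GRCh38), which holds 5935 of the identifiers and lacks 83; it need not be the authors' annotation. Levels in C and V were derived as the pair of means whose average is the listed mean and whose ratio is the listed fold change. This assumes equally many libraries on each side and gives no error. Of the 5380 called genes, 1181 had a derived lower level under 1 normalised count, where the fitted fold change depends on the estimator and is no bound. Exon lengths for 1 check in the closing part are union lengths in that release. The median standard error of called genes was 1.21 on the log2 scale below a mean of 10, 0.45 from 10 to 100, 0.15 from 100 to 1000 and 0.09 above, so genes with more reads are the better determined.

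The design written before the data were examined foresaw library-level values, with limma or a count model for genes and camera for gene lists. For a table of the authors' own comparison it prescribed no test of genes, values described as listed and sizes by fold, and this was followed. In place of camera, each list with at least 5 called members was tested with Fisher's exact test, two-sided, on the division of its called members between C and V against that of the other called protein-coding genes, with Benjamini-Hochberg adjustment over the 31 lists tested. This test was chosen after the table was seen. It asks about direction among called genes only and treats genes as independent, which makes its p-values too small. The 40 lists themselves were fixed beforehand. Counts adjusted over the list alone used the listed p-values with unlisted members set to 1; over all lists both counts came to 365 memberships, and they differed in 6 lists.

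The rule for named genes, also fixed beforehand, took the 10 called genes with the largest fold change in each direction among those with a symbol and a mean of at least 50 in the higher group, a fixed set of 15 genes of androgen action and drug metabolism, and up to 4 members of each list with the smallest p. Its requirement that the libraries of the groups do not overlap could not be applied. The derived level stood for the group mean. Some genes and 1 list that were fixed beforehand are not reported here. Genes outside the rule are said to be so where they appear.

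Tests were run in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. The list test was tested on simulated data: with random directions for the 5380 called genes, 3 of 100 simulations had any of the 31 lists past the threshold. Directions were drawn independently for each gene, so this count cannot show the error that arises when members of a list move together. With all called members of the mitosis, glycolysis and p53 lists (26, 6 and 8 genes) set to higher in C, each list passed in 100 of 100 simulations. With them set to higher in V, the mitosis list passed in 100 of 100 and the glycolysis and p53 lists in 0 of 100, since most called protein-coding genes are higher in V, so the test could not find V lists of these sizes.

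Of the tests of explanations, 3 were dropped or replaced after their results were known, because they repeated the pattern they were to explain or left out called genes: the share of small structured RNAs higher in C, the count of Y-linked genes lower in V, and the standard errors of interferon genes. The comparison of histone with DNA replication genes replaced the first of them when both medians were already known. It was at first read as support for a difference in library preparation, and then taken to decide nothing, because a shift of the cell cycle could give the same result.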

Results

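The series measured gene expression by RNA sequencing in C4-2B, an established human prostate cancer line derived from LNCaP cells that grows under castrate androgen levels. It holds 3 libraries of the parental line and 3 of a subline selected in stepwise higher abiraterone, from 1 to 20 µM, over at least 6 months and then kept in 5 µM drug. Abiraterone inhibits CYP17A1, the enzyme that commits pregnenolone and progesterone to androgen synthesis. The comparison the design implies asks how expression in the selected subline differs from that in the parental line. The values used here are the authors' own DESeq2 comparison of a condition C with a condition V, listing 6018 genes with no value per library. Depth per library is therefore unknown.

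Per the header of the authors' deposited table, C stands for control and V for vehicle, and a positive log2 fold change marks higher expression in C. The titles of the 3 parental libraries carry the letter V, and no title carries a C apart from the name of the line. The parental cells were passaged in DMSO, a vehicle, and are also called the control in the series text. If the table compares the groups of the series, C would by elimination be the selected subline, against the header's word control, and the directions below would then read as higher in the selected subline for C. The header itself does not tie C to either cell line, so each direction is given below as higher in C or higher in V and is not translated into resistant or parental. Values in parentheses after a gene are the log2 fold change of C over V ± its standard error, both as listed. A gene was called when its listed adjusted p was under 0.05. Levels per side are not listed and were derived from the listed mean and fold change, taking both sides as equally large.

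Proliferation genes were higher in C, and interferon, antigen-presentation, stress and inflammatory genes were higher in V. Of the 5380 called genes, 2771 were higher in C and 2609 were higher in V. Gene type divided the directions. Among the 2736 called protein-coding genes, 934 (34.1%) were higher in C and 1802 were higher in V. Among the 2644 called genes of other types, 1837 (69.5%) were higher in C (Fisher's exact test, two-sided, p = 2.62e-151; genes are not independent replicates). The share of calls higher in C was thus 51.5% over all types and 34.1% in protein-coding genes.

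**Figure D1:**
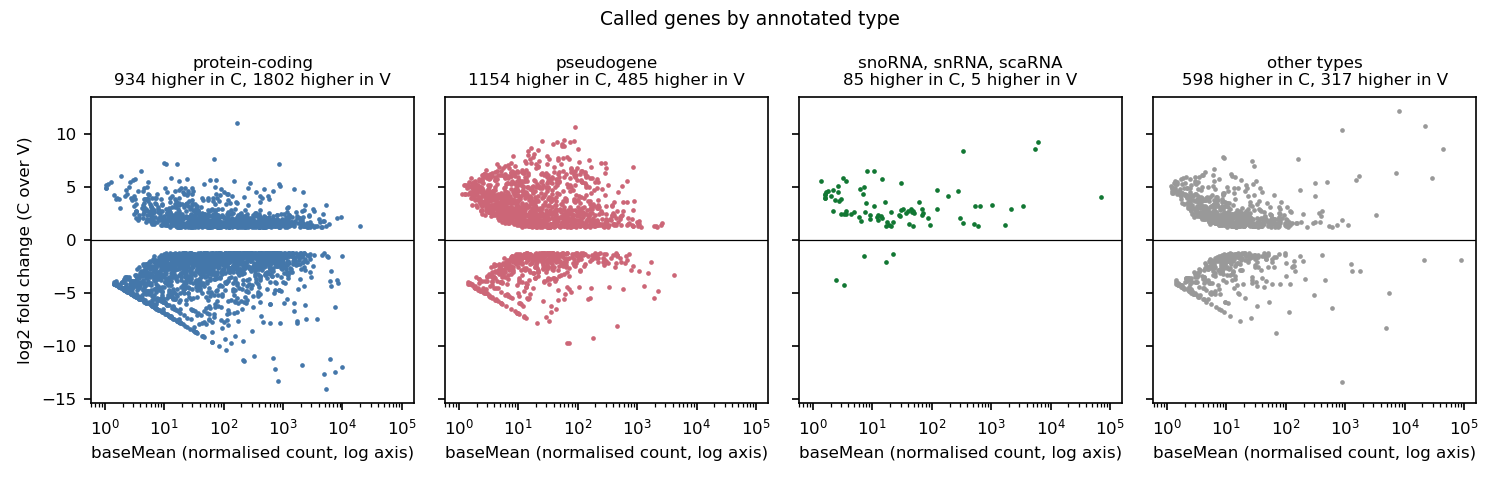
Log2 fold change of C over V (vertical axis) against the mean normalised count on a log axis, for the called genes of the authors' deposited table, 1 point per gene, in 4 panels by gene type. Protein-coding points lie mostly below 0 (1802 of 2736), and 85 of the 90 snoRNA, snRNA and scaRNA points lie above 0; the empty band around 0 is the table's own minimum fold change.

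Interferon-stimulated genes were higher in V wherever they were called. All 29 called members of the 34-gene list were higher in V, with a median log2 fold change of -5.78 (adjusted p = 6.1e-05, Fisher's exact test of direction against other called protein-coding genes). The 4 members with the smallest p in the authors' deposited table were DDX58 (-7.47 ± 0.13), which encodes the RNA sensor RIG-I, IFIH1 (-5.93 ± 0.13), which encodes the RNA sensor MDA5, ISG15 (-6.38 ± 0.15), a ubiquitin-like modifier, and HERC5 (-7.63 ± 0.20), its ligase. The derived level of ISG15 in the authors' deposited table was 174 normalised counts in C and 14540 in V. STAT2, IRF9, IFITM1 and IFITM2 were not listed in the table used here.

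The 10 genes shifted farthest toward V were RSAD2, CCL5, IFIT3, OASL, CXCL10, IFIT2, APOL1, KRT6A, CXCL11 and IFIT1. In the authors' deposited table their log2 fold changes ran from -14.12 ± 1.02 for RSAD2, an antiviral enzyme, to -11.29 ± 0.35 for IFIT1, which binds foreign RNA. IFIT1, IFIT2 and IFIT3 are neighbours on chromosome 10 in GENCODE release 29 (GRCh38), at 89392546 to 89406486, 89283694 to 89309276 and 89327894 to 89340971. The derived levels from the authors' deposited table were 4.71 in C and 19412 in V for IFIT2, and 5.00 in C and 12491 in V for IFIT1. For RSAD2, CCL5, CXCL10, KRT6A and CXCL11 the derived level in C was under 1 normalised count, so the size of their fold changes is poorly determined.

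Antigen presentation and inflammatory genes lay on the same side. All 18 called members of the 20-gene antigen presentation list were higher in V (adjusted p = 0.00316). They included the class I light chain B2M (-3.93 ± 0.06), the heavy chain HLA-B (-3.16 ± 0.11) and the peptide transporter TAP1 (-3.04 ± 0.12), as listed in the authors' deposited table; HLA genes are near-identical copies, so the division of reads among them is uncertain. All 13 called members of the 26-gene NF-kB and cytokine list were higher in V (adjusted p = 0.0163), led in the authors' deposited table by the apoptosis inhibitor BIRC3 (-6.71 ± 0.16), the feedback regulator TNFAIP3 (-4.34 ± 0.19), the cytokine LIF (-3.06 ± 0.19) and the inhibitor NFKBIA (-1.42 ± 0.10). The NF-kB call ended with a log2 fold change of at least 2 (adjusted p = 0.152) and with a mean of at least 100 (adjusted p = 0.133; range over the alternatives 0.000313 to 0.152), and the antigen presentation call with a mean of at least 100 (adjusted p = 0.0615; range 1.32e-05 to 0.0615). The low end of both ranges came from a background of all called genes, which favours V lists through gene type alone. Of the 16 leukocyte markers, 6 were called and all 6 were higher in V (adjusted p = 0.16). The levels of these 6 were low, with a highest derived V level of 35.7 normalised counts for PTPRC in the authors' deposited table, against 11780 for B2M. Of the 12 endothelial markers, 3 were called, all higher in V: ROBO4 (-6.38 ± 1.30), PECAM1 (-6.49 ± 1.35) and ESAM (-2.67 ± 0.61) in the authors' deposited table. Their levels were low too, with derived V levels of 13.4, 14.9 and 30.8 normalised counts. ROBO4 and PECAM1 had derived C levels under 1, so the size of their fold changes is poorly determined.

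Stress and early-response genes were also higher in V. All 16 called members of the 24-gene NRF2 target list were higher in V (adjusted p = 0.00759), with the iron storage chains FTH1 (-4.35 ± 0.10) and FTL (-1.78 ± 0.09), the heme oxygenase HMOX1 (-4.05 ± 0.12) and the pentose phosphate enzyme PGD (-1.76 ± 0.08) leading in the authors' deposited table. FTH1 and FTL share reads with near-identical processed pseudogenes, and 9 of the 10 called FTH1 copies were likewise higher in V, whereas of the 2 called FTL copies 1 was higher in C and 1 higher in V. All 11 called members of the 29-gene integrated stress response list were higher in V (adjusted p = 0.0418), among them the transcription factors ATF3 (-4.01 ± 0.10), NUPR1 (-3.05 ± 0.10), CEBPB (-3.21 ± 0.12) and DDIT3 (-2.51 ± 0.11) in the authors' deposited table. This call ended when the 95% interval of the fold change had to lie beyond a log2 of 1 (adjusted p = 0.0726) and with a log2 fold change of at least 2 (adjusted p = 0.256; range over the alternatives 0.00107 to 0.256), and the NRF2 call ended with the latter (adjusted p = 0.256; range 4.72e-05 to 0.256). Of the 25 immediate early genes, 20 were called, 19 of them higher in V (adjusted p = 0.0115), and 21 were called when adjusted over the list alone. KLF4 (-5.54 ± 0.13), DUSP1 (-4.79 ± 0.13) and JUNB (-3.03 ± 0.09) were among those higher in V in the authors' deposited table, while MYC (1.42 ± 0.09) was the single member higher in C. All 11 called members of the 22-gene YAP and TGF-beta list were higher in V (adjusted p = 0.0418), led by ID1 (-2.79 ± 0.09), BAMBI (-3.15 ± 0.11), ID2 (-2.71 ± 0.15) and CCN1 (-2.73 ± 0.19) in the authors' deposited table. With a log2 fold change of at least 2 and with a mean of at least 100, the immediate early call ended (adjusted p = 0.112 and 0.104; range 5.68e-05 to 0.112), as did the YAP and TGF-beta call (adjusted p = 0.256 and 0.0615; range 0.00107 to 0.256). The low end of each range given for these stress and early-response lists came from a background of all called genes, which favours V lists through gene type alone.

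On the C side stood the cell-cycle genes. All 26 called members of the 29-gene mitosis list were higher in C (adjusted p = 1.8e-11), with a median log2 fold change of 1.67; 27 were called when adjusted over the list alone. The smallest p values in the authors' deposited table belonged to the kinetochore protein CENPF (2.37 ± 0.05), the proliferation antigen MKI67 (2.69 ± 0.07), the topoisomerase TOP2A (1.83 ± 0.05) and the kinase CDK1 (2.30 ± 0.07). All 25 called members of the 31-gene DNA replication list were higher in C (adjusted p = 2.68e-11), headed in the authors' deposited table by the replicative helicase subunits MCM4 (2.07 ± 0.07), MCM3 (2.11 ± 0.08), MCM2 (2.05 ± 0.09) and MCM7 (1.73 ± 0.08). All 12 called members of the 25-gene DNA repair list were higher in C (adjusted p = 1.85e-05), with BRCA1 (1.81 ± 0.08), FANCD2 (1.93 ± 0.08), PARP1 (1.33 ± 0.06) and FANCI (1.25 ± 0.07) first in the authors' deposited table. The ribosome biogenesis and MYC target list had 7 called members of 26, all higher in C (adjusted p = 0.00275), including NPM1 (1.29 ± 0.05), PA2G4 (1.42 ± 0.08) and MYC itself in the authors' deposited table. All 6 called members of the 22-gene glycolysis list were higher in C (adjusted p = 0.00607), LDHA (1.69 ± 0.08), GPI (1.51 ± 0.08), GAPDH (1.28 ± 0.07) and PGK1 (1.22 ± 0.08) being the first 4 in the authors' deposited table. With a log2 fold change of at least 2, the mitosis list kept 4 called members and the DNA repair, ribosome biogenesis and glycolysis lists kept 0, fewer than the 5 that a test needs.

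Replication-dependent histone genes had 23 called members of 33, all higher in C (adjusted p = 1.61e-10), with a median log2 fold change of 2.22. H2BC5 (2.25 ± 0.08), H3C2 (2.38 ± 0.09), H2AC13 (2.67 ± 0.10) and H1-5 (3.28 ± 0.13) had the smallest p values in the authors' deposited table. Histone messages lack a poly(A) tail, as do snoRNAs, of which 47 of 48 called were higher in C. Small nuclear RNAs were higher in C for 32 of 36 called genes.

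**Figure D2:**
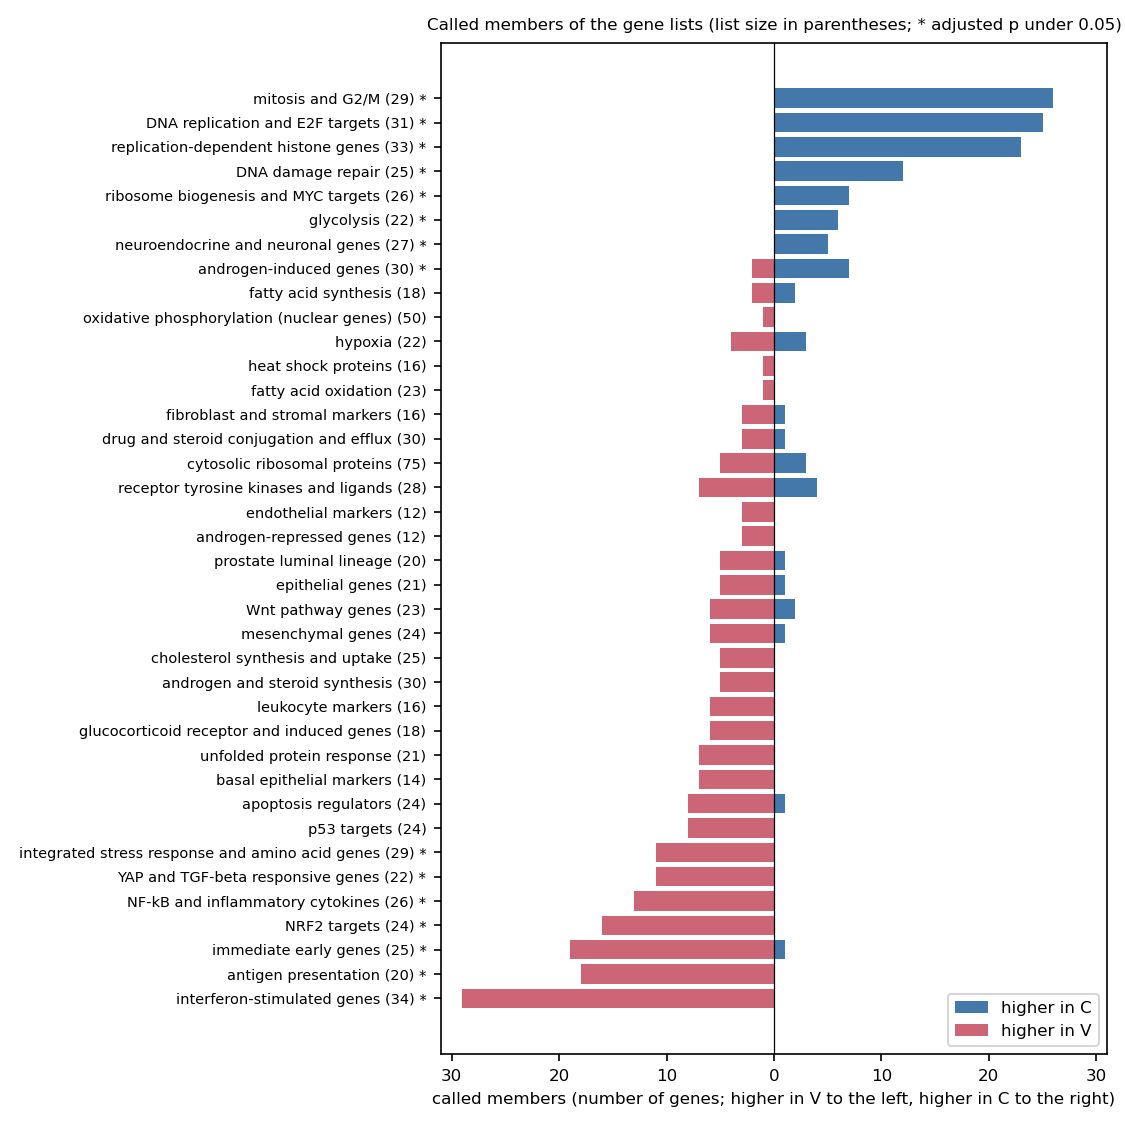
Number of called members higher in C (right) and higher in V (left) for 38 gene lists with a called member, list size in parentheses; an asterisk marks an adjusted p under 0.05. Interferon-stimulated genes lie wholly on the V side with 29 genes, and the mitosis list wholly on the C side with 26.

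Called androgen-induced genes were mostly higher in C, and the 3 called androgen-repressed genes were higher in V. Of the 30 androgen-induced genes, 9 were called, 7 higher in C and 2 higher in V (adjusted p = 0.0226). KLK3, which encodes prostate-specific antigen and lies at 50854915 to 50860764 on chromosome 19 in GENCODE release 29 (GRCh38), and its neighbour KLK2 were higher in C, at 2.17 ± 0.07 and 2.59 ± 0.08 in the authors' deposited table. MPHOSPH9 (1.70 ± 0.08) was also higher in C and ALDH1A3 (-1.44 ± 0.08) higher in V in the authors' deposited table. The call ended in 4 of the 8 alternative settings that change the list test, among them a background of all called genes (adjusted p = 0.201; range 0.00932 to 0.201). TMPRSS2 and FKBP5 were not listed in the table used here. The androgen-repressed list had 3 called members of 12, CCN3 (-10.37 ± 1.19), SERPINI1 (-1.64 ± 0.37) and MET (-1.60 ± 0.57), all higher in V in the authors' deposited table. The derived C level of CCN3 was 0.166 normalised counts, so the size of its fold change is poorly determined.

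Steroid-metabolising genes that were called were mostly higher in V. The androgen and steroid synthesis list had 5 called members of 30, all higher in V (adjusted p = 0.241). They included the sulfatase STS (-3.16 ± 0.11) and the ketosteroid reductases AKR1C2 (-7.96 ± 1.19), AKR1C1 (-7.54 ± 1.19) and AKR1C3 (-5.69 ± 1.03), as listed in the authors' deposited table. The AKR1C genes are near-identical neighbours, so their division of reads is uncertain. They are also called members of the NRF2 target list, so the steroid synthesis and NRF2 lists are not separate patterns. For AKR1C3 the derived level from the authors' deposited table was 9.45 normalised counts in C and 488 in V. For AKR1C2 and AKR1C1 the derived C levels were 0.399 and 0.967, so the size of their fold changes is poorly determined. CYP17A1, the target of the drug, was listed in the authors' deposited table at a mean of 0.759 normalised counts with p = 0.0493 and no usable adjusted p, and was not called. HSD3B1, SRD5A1, UGT2B15, UGT2B17 and ABCB1 were not listed in the table used here. The conjugation and efflux list had 4 called members of 30: CYP1A1 (-3.62 ± 0.23), GSTA1 (-2.89 ± 0.28), CYP3A5 (-7.58 ± 1.04) and UGT2B28 (3.42 ± 0.62) in the authors' deposited table, the last one alone higher in C. The derived C level of CYP3A5 was 0.600, so the size of its fold change is also poorly determined. The glucocorticoid receptor and induced gene list, which also holds enzymes, had 6 called members of 18, all higher in V (adjusted p = 0.16). Among them were the receptor NR3C1 (-4.98 ± 0.75), DUSP1 (-4.79 ± 0.13), HSD11B2 (-3.20 ± 0.12), ERRFI1 (-1.39 ± 0.11) and SGK1 (-2.63 ± 0.27) in the authors' deposited table. Of these, DUSP1 is also in the immediate early list.

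**Figure D3:**
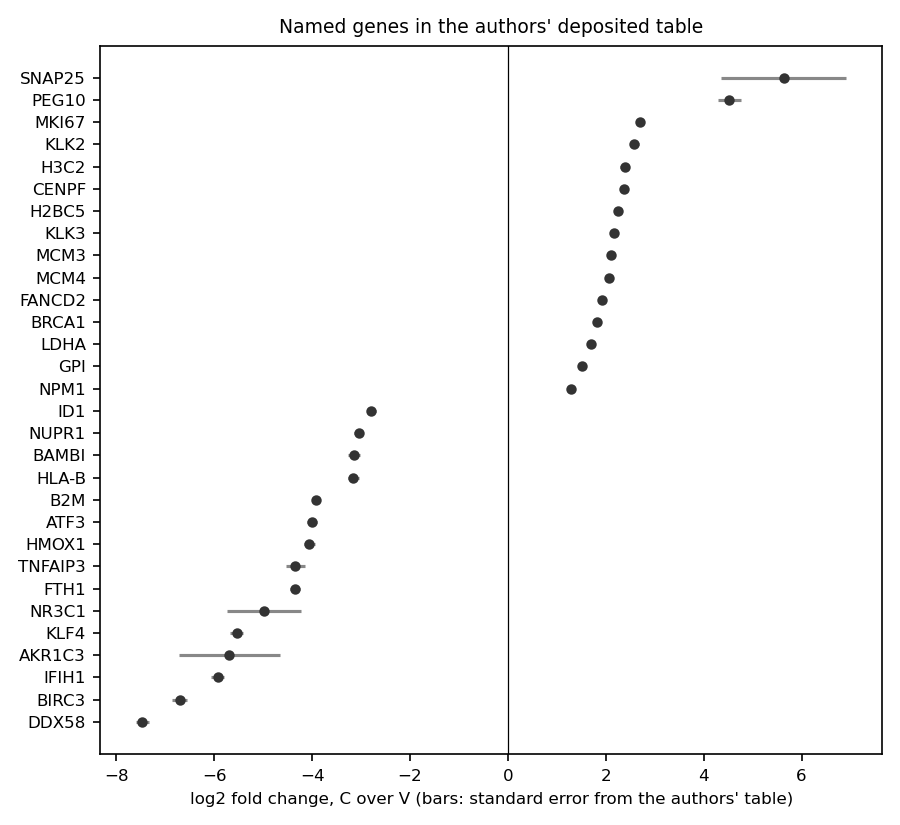
Log2 fold change of C over V with its standard error (bars) from the authors' deposited table, for the 2 members farthest from 0 in standard errors of each list past the threshold and the called genes named in advance. DDX58 lies lowest at -7.47 and SNAP25 highest at 5.64, where the bar is wide.

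Neuronal and lineage genes gave smaller groups. The neuroendocrine list had 5 called members of 27, all higher in C (adjusted p = 0.013), and 4 when adjusted over the list alone: PEG10 (4.52 ± 0.23), SNAP25 (5.64 ± 1.28), SRRM4 (5.06 ± 1.25) and SCG5 (2.77 ± 0.71) led in the authors' deposited table. SNAP25 and SRRM4 had standard errors above 1 at derived levels of 145 and 1718 normalised counts in C and 2.91 and 51.5 in V in the authors' deposited table, so the size of their fold changes is poorly determined, and with only 5 members the call ended in 6 of the 8 alternative settings that change the list test. SYP and CHGA were not listed in the table used here. Basal epithelial markers had 7 called members of 14, all higher in V (adjusted p = 0.16), 8 when adjusted over the list alone, among them LAMB3 (-5.84 ± 0.37), ITGB4 (-2.27 ± 0.21), KRT6A (-11.42 ± 1.18) and KRT17 (-7.65 ± 1.23) in the authors' deposited table. The luminal list had 6 of 20 called, 5 higher in V (adjusted p = 0.77), with AGR2 (-2.90 ± 0.10), MSMB (-5.43 ± 0.26) and SLC44A4 (-1.38 ± 0.08) among them in the authors' deposited table. Mesenchymal genes had 7 of 24 called, 6 higher in V (adjusted p = 0.538; 6 called when adjusted over the list alone), with ITGA5 (-1.72 ± 0.11) and ZEB1 (-6.20 ± 1.32) higher in V and LOX (2.40 ± 0.27) higher in C in the authors' deposited table. Epithelial genes had 6 of 21 called, 5 higher in V (adjusted p = 0.77), led by CLDN4 (-2.45 ± 0.09), CLDN7 (-1.40 ± 0.06), OCLN (-2.05 ± 0.12) and KRT8 (-1.45 ± 0.10) in the authors' deposited table. Fibroblast markers had 4 of 16 called, 3 higher in V, COL1A1 (-2.02 ± 0.21), ACTA2 (-1.89 ± 0.46) and COL5A1 (-5.29 ± 1.41), with PDGFRB (1.78 ± 0.62) higher in C in the authors' deposited table. KRT6A, KRT17, ZEB1 and COL5A1 had derived C levels under 1 normalised count, so the size of their fold changes is poorly determined.

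Several lists had all or nearly all called members on 1 side without passing the list test. All 8 called p53 targets of 24 were higher in V (adjusted p = 0.111), with the secreted factor GDF15 (-4.07 ± 0.10), the cyclin-dependent kinase inhibitor CDKN1A (-2.86 ± 0.07), BBC3 (-2.78 ± 0.17) and BTG2 (-1.43 ± 0.09) first in the authors' deposited table. All 7 called unfolded protein response genes of 21 were higher in V (adjusted p = 0.16), among them XBP1 (-1.81 ± 0.07), HSPA5 (-1.49 ± 0.06), HERPUD1 (-1.62 ± 0.07) and DNAJB9 (-2.62 ± 0.14) in the authors' deposited table. Cholesterol synthesis had 5 of 25 called, all higher in V (adjusted p = 0.241), with HMGCS1 (-2.67 ± 0.10), TM7SF2 (-1.54 ± 0.09), SC5D (-1.99 ± 0.16) and MVD (-1.24 ± 0.15) in the authors' deposited table. Apoptosis regulators had 9 of 24 called, 8 higher in V (adjusted p = 0.241), with MCL1 (-1.51 ± 0.07) and BCL2L1 (-1.51 ± 0.07) higher in V and BIRC5 (1.59 ± 0.08) higher in C in the authors' deposited table. With all called genes as the background these 4 lists passed, and so did the androgen and steroid synthesis, glucocorticoid, basal epithelial and leukocyte lists, 8 in all (adjusted p from 0.00786 to 0.0415; range of the 8 over all alternatives 0.00786 to 0.767). Of all called genes 51.5% were higher in C, against 34.1% of the protein-coding ones. That background therefore favours V lists through gene type alone, and these 8 passes are no separate support for the lists. In simulations the main test passed 0 of 100 times for lists of 6 and 8 called members all set to higher in V, so missing the threshold says little about V lists this small.

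The remaining lists went both ways or had few called genes. Receptor tyrosine kinases and ligands had 11 of 28 called, 4 higher in C and 7 higher in V (adjusted p = 1); IGF1R (2.99 ± 0.07), IGF1 (3.55 ± 0.17) and FGFR3 (2.20 ± 0.16) were higher in C and VEGFA (-1.21 ± 0.11) higher in V in the authors' deposited table. Wnt pathway genes had 8 of 23 called, 2 higher in C and 6 higher in V (adjusted p = 0.773), with FZD4 (-1.40 ± 0.08), AXIN2 (-2.37 ± 0.24), RNF43 (-1.87 ± 0.26) and WNT5A (-1.44 ± 0.27) first in the authors' deposited table. Hypoxia genes had 7 of 22 called, 3 higher in C and 4 higher in V (adjusted p = 0.771; 6 called when adjusted over the list alone), such as PDK1 (1.75 ± 0.12) and PFKFB4 (1.66 ± 0.15) against BHLHE40 (-1.67 ± 0.10) and VEGFA in the authors' deposited table. Cytosolic ribosomal proteins had 8 of 75 called, 3 higher in C and 5 higher in V (adjusted p = 1), RPL27A (1.94 ± 0.07), RPL12 (1.68 ± 0.07), RPL21 (-2.23 ± 0.11) and RPL14 (1.21 ± 0.06) having the smallest p in the authors' deposited table; all share reads with pseudogene copies and are uncertain. Fatty acid synthesis had 4 of 18 called, SREBF1 (1.44 ± 0.07) and FADS2 (1.23 ± 0.08) higher in C and ACSL1 (-1.35 ± 0.06) and ME1 (-1.64 ± 0.09) higher in V in the authors' deposited table. Fatty acid oxidation, oxidative phosphorylation and heat shock proteins had 1 called gene each, of 23, 50 and 16, all higher in V: ACOX3 (-1.96 ± 0.16), NDUFC2 (-1.72 ± 0.21) and DNAJB4 (-2.23 ± 0.20) in the authors' deposited table. None of the 15 mitochondrially encoded genes was listed in the table used here.

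The 10 genes shifted farthest toward C under the naming rule were H2BC10, RPS10P9, HNRNPA1P36, RPL7AP73, NDUFB4P7, RPL30P2, RPS3AP30, RNVU1-29, PPIAP60 and NACAP2. H2BC10 encodes a histone, RNVU1-29 a U1 small nuclear RNA variant, and the other 8 are processed pseudogenes, all near-identical to other genes and therefore uncertain. Their log2 fold changes in the authors' deposited table ran from 9.02 ± 1.21 for NACAP2 to 10.99 ± 1.20 for H2BC10, and only RNVU1-29 had a derived V level above 1 normalised count. Among protein-coding genes without such copies, TENM1 (7.17 ± 0.18), a cell-surface adhesion protein, and SYT4 (4.81 ± 0.12), a synaptotagmin, were higher in C in the authors' deposited table; both were singled out after their values were seen.

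Of the 40 lists, 31 had at least 5 called members and were tested, and 15 passed, 8 toward C and 7 toward V. The test of direction replaced the planned one after the table was seen, and members of a list are not independent. Calls of the interferon, DNA replication and histone lists held in all 8 alternative settings that change the list test, while each of the other 12 was lost in at least 1, most often under a minimum log2 fold change of 2.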

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

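The tests of an adjusted p under 0.01 and of an absolute log2 fold change of at least 1 were planned; every other alternative and the list test itself were chosen after seeing the data. No paired analysis was possible because the table has no value per library, and for the same reason the settings foreseen for pseudocount, low-value filters, scaling, trend, other count tools, left-out libraries and camera were not run. A minimum absolute log2 fold change of 1 removed no gene and tests nothing, since the table already starts at 1.20. With an adjusted p under 0.01, 4489 genes were called (2295 higher in C, 2194 higher in V) and 14 lists passed. Counts fell by more than 1.5 times in 3 settings, each of which tests fewer genes by construction. With an absolute log2 fold change of at least 2, 3228 genes were called, 1649 higher in C and 1579 higher in V, and 5 lists passed. With a mean of at least 100, 1585 genes were called, 709 higher in C and 876 higher in V, and 9 lists passed, without the androgen-induced, neuroendocrine, antigen presentation, NF-kB, immediate early and YAP lists. The integrated stress response list was also lost with the 95% interval beyond a log2 of 1. With protein-coding genes only, 2736 were called, 934 of them higher in C, and the list test was repeated as it was except for 1 list, the histone genes. Interferon-stimulated genes, DNA replication and histone genes were past the threshold in all 8 settings that change the list test, and the neuroendocrine list in 2, mostly because fewer than 5 members were left. With all called genes as the background, 21 lists passed, 8 of them gained, without the androgen-induced and neuroendocrine lists. This background holds the other gene types, which lie mostly on the C side, so it favours V lists through gene type alone. Depth is unknown; the 1540 called genes with a mean under 10 had a median standard error of 1.21 on the log2 scale, which limits what can be said of their sizes.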

Other observations

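All tests of explanations in this part were chosen after the values had been seen, and so were the genes named in it. Genes for interferons themselves were higher in V. IFNB1, which encodes interferon beta, and the lambda interferon genes IFNL1, IFNL2 and IFNL3 had log2 fold changes of -9.15 ± 1.20, -10.03 ± 1.19, -8.23 ± 1.21 and -7.83 ± 1.22 in the authors' deposited table. Their derived V levels in the authors' deposited table were 92.5, 171, 49.0 and 37.0 normalised counts, with C levels under 1. IFNL2 and IFNL3 are near-identical copies and uncertain. GBP1, an interferon-induced GTPase, was higher in V at -6.82 ± 0.47 in the authors' deposited table. The nuclear noncoding RNAs MALAT1 and NEAT1 were also higher in V, at -1.94 ± 0.11 and -1.87 ± 0.18 in the authors' deposited table.

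A set of 21 called protein-coding genes had standard errors above 1 despite a mean of at least 50 and a derived lower level of at least 1, where 1537 such genes had a median of 0.15. Of the 21, 12 were higher in C, including the neuronal genes CPLX2 (5.32 ± 1.29) and SLC6A15 (4.32 ± 1.39) and the receptor LGR5 (4.64 ± 1.35) in the authors' deposited table. Among those higher in V were SPINK1 (-6.91 ± 1.19), SYK (-6.64 ± 1.19) and CX3CL1 (-6.27 ± 1.20) in the authors' deposited table. Spread between libraries and low levels on 1 side, such as a derived C level of 2.49 for SPINK1, both widen such errors, and the authors' deposited table does not separate them for the set. For SRRM4, which meets the same limits, the lower level was not small: its standard error was 1.25 at derived levels of 1718 in C and 51.5 in V. Called genes with a mean of 10 to 100 had a median standard error of 0.45.

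Small structured RNAs and, less uniformly, pseudogenes were higher in C, with 94.4% of the 90 called snoRNA, snRNA and scaRNA genes, 71.3% of the 1434 processed and 65.4% of the 191 unprocessed pseudogenes on that side, against 69.5% of all called genes other than protein-coding. SNORD3A reached 4.00 ± 0.47 and SNORA73B 2.87 ± 0.13 in the authors' deposited table. Another 4 unnamed genes on chromosome 21 between 8210384 and 8438551, typed as lincRNA in GENCODE release 29 (GRCh38), had derived C levels from 1753 to 88677 against 1.35 to 239 in V. Which RNA the reads of these 4 genes come from was not tested. Genomic DNA in the C libraries at the median density of the 80 sense-intronic genes higher in C, 13.4 per kb, is argued against. At that density the exons of 370 called protein-coding genes with a derived C level under 1 normalised count would have at least 10. Because the 80 genes were taken for being higher in C, their density may be too high, and a lower amount of DNA was not tested. Whether RNA selection or library preparation differed between the sides or the cell lines differ cannot be told apart for these RNAs, because no label gives the preparation by side. The histone genes, whose messages also lack poly(A) tails, decide nothing. Their median log2 fold change was 0.50 above that of the DNA replication genes (permutation test, p = 0.00116, 23 and 25 genes). The DNA replication genes were themselves higher in C, and a shift of the cell cycle, which was not tested, could raise histone messages as well. Reads shared between parent genes and copies may account for part, since 72.8% of the 213 processed pseudogenes with a called parent had its direction (Fisher's exact test, two-sided, p = 3.59e-14). Direction was shared by 78 of 88 where the parent was higher in C, but by only 77 of 125 where it was higher in V. All 3 called RPS10 copies were higher in C (summed level 506.7 in C, 6.03 in V) and RPS10 itself higher in V (43.5 in C, 275.9 in V). RPL7 and RPL21 were also higher in V, with 11 of 12 and 8 of 12 called copies higher in C. The 846 named pseudogenes without a called parent (74.0% higher in C) stay open.

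Interferon-stimulated genes were higher in V together with leukocyte markers. Leukocytes in the V libraries are argued against as the source, since the median derived V level of the 29 called interferon genes was 44.0 times that of the 6 called leukocyte markers (908.5 against 20.7 normalised counts), with LYZ at 22.0 and CD74 at 14.8 in the authors' deposited table. An interferon response of the V cells themselves, to the selection, the drug, the vehicle or another stimulus, stays open as a hypothesis and was not tested, nor was a difference in culture or handling. The standard error was above 1 in 6 of the 29, each with a derived C level under 1, and at most 0.647 in the other 23, but how much each library contributes stays open without values per library.

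Y-linked genes were lower in V. Of a list of 12 such genes written for this test, 9 were called and 9 were lower in V, by a median of 4.81 on the log2 scale, which leaves 3.56% of the C level. A single share of V cells that keep the chromosome, with C-like expression per cell and no reads from other genes, is argued against. The fold changes differed beyond their errors (Cochran's Q, p = 7.97e-19), from 3.10 ± 0.21 for PRKY to 5.55 ± 0.42 for UTY in the authors' deposited table. The test cannot decide on a retained share of cells whose expression differs from C gene by gene, since that would also give unequal fold changes. Loss of the chromosome in V cells, outgrowth of a subclone, reads from X-linked copies and a difference in cell line history between the sides stay open and were not tested on other values.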
